A study of Mus musculus with 2 samples.

How the data were processed

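RNA from mouse CGR8 embryonic stem cells, a feeder-free line kept in serum with leukaemia inhibitory factor, was sequenced after transfection with a negative control siRNA or with an siRNA against Set1a, 72 hours being given as the transfection time. Each group held 1 library, 2 in total, and groups were taken from the transfection label of each sample. The deposited tables list 28430 RefSeq transcripts, the same ones for both libraries, each with 1 value. No header names the unit; RPKM, the read number scaled by transcript length and library depth, was inferred from the deposited values, because value multiplied by transcript length moved in whole steps. Per the submitters' processing notes, CASAVA, TopHat, TopHat2 2.0.12 and SAMtools 0.1.16 were used with genome build mm9, without the role or order of each. The program that counted reads, its treatment of strand and its rule for reads that match several places are not given in the sources used here.

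Depth was recovered from the step that 1 read makes in low values. It came to about 6660000 reads for the control siRNA library and 6420000 for the Set1a siRNA library, a ratio of 0.965. Of transcripts with 1 to 5 reads, 74.7% in the control siRNA library and 73.6% in the Set1a siRNA library lay within 0.1 of a whole read, against 20% for values placed at random. Lengths came from another annotation release than the authors', so read numbers are approximate. Summed over all transcripts, value times length made 100.4% and 100.5% of those depths, and with 1 transcript per gene 80.3% and 80.2%.

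Symbols were taken from a GRCm38.p6 RefSeq gene table and GENCODE M21, and 27957 transcripts (98.3%) received one. As that build differs from mm9, it served for symbols, transcript lengths, sequences and GC content, and no coordinates are given. Each of 22421 genes was represented by its transcript with the most reads. The fold of a gene was log2((Set1a siRNA RPKM + 1)/(control siRNA RPKM + 1)), which understates changes of low genes, and 11786 genes with a mean of at least 1 RPKM entered. Ratios of the deposited RPKM are given with exact Clopper-Pearson 95% intervals from the recovered reads. These intervals cover counting error only. They take each read as counted at 1 transcript, which is not known for near-identical copies. For a gene with 0 reads in a library, 3 reads were used as its limit there.

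With 1 library per group there is no replicate check and no p-value. Genes were counted by a rule of size, at least 2-fold either way. Before the data were examined, 32 gene lists were fixed, and 586 of their 589 entries were found among the genes. Setd1b, Rhox5 and H19 were not analysed here. For the 30 lists with at least 5 measured members, the median log2 fold was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. A list stood apart when its median lay outside the central 95% of its random lists, and 1.5 of the 30 lists would do so by chance if genes varied independently. Genes of a list may vary together between any 2 cultures. How many lists would then stand apart by chance was not measured.

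Genes were named by a rule also fixed before the data were examined: Setd1a and related methyltransferases; the 12 highest and 12 lowest folds at a mean of at least 5 RPKM; the 12 largest changes at a mean of at least 50 RPKM; the 4 members farthest out in each list that stood apart; 12 markers of pluripotency and lineage; and up to 4 members past 2-fold in any other list. Some genes that the rule names are not reported here. Other names are said to have been chosen after their values were seen.

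The scripts were tested on simulated Poisson counts for 11661 genes at the recovered depths. For the comparison of the Set1a siRNA library with the control siRNA library, 100% of 50 genes set 4-fold higher and 94% of 50 genes set to a fold of 0.25 were called, as were 22% of 50 genes set exactly 2-fold higher and 20% of 50 genes set to a fold of 0.5, since the added 1 RPKM pulls such genes below the threshold. Of 200 random lists with no change, 12 (6%) lay outside the central 95%.

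Settings chosen before the data were examined to be varied were pseudocounts of 0.1 and 5, no floor and a floor of 5 RPKM, median-of-ratios scaling, scaling without the 50 most abundant genes, 1.5-fold and 3-fold rules, list means, and random lists without matching. Settings added after seeing the data were the transcript with the highest RPKM per gene, transcripts of at least 200 nucleotides, genes with at least 30 reads over both libraries, removal of a cubic trend in GC content and log length fitted on genes of at least 5 RPKM and 200 nucleotides, near-identical families counted once, and a counting interval that excludes 1. Near-identical transcripts were found with BLAST 2.17.0, by matching genes past 2-fold to every listed transcript of at least 200 nucleotides at 90% identity or more over at least 50% of the shorter one. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.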

Results

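Transcript levels were measured in 2 RNA-seq libraries of mouse CGR8 embryonic stem cells, 1 from cells given a negative control siRNA and 1 from cells given an siRNA against Set1a. Set1a, listed as Setd1a, encodes a methyltransferase of histone H3 lysine 4. The comparison asked how lowering SET1A affects expression genome-wide. The deposited RPKM values corresponded to depths of about 6660000 reads for the control siRNA library and 6420000 for the Set1a siRNA library, with a median of 175 control reads for a gene above the floor of 1 RPKM. Every difference below is between these 2 libraries and has no replicate check.

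Setd1a was at 14.2 RPKM in the control siRNA library and 11.97 RPKM in the Set1a siRNA library. The ratio was 0.846, with a counting interval of 0.746 to 0.959, from 559 and 456 reads. The direction was that of the labels, but the difference was modest: of 7922 genes with a mean of at least 5 RPKM, 1035 (13.1%) had a lower fold than Setd1a. The related methyltransferase genes lay closer to 1, and each of their counting intervals included it. The ratio was 0.937 for Kmt2d (0.857 to 1.02), 0.965 for Kmt2c (0.884 to 1.05), 0.968 for Kmt2a (0.869 to 1.08) and 0.986 for Kmt2b (0.879 to 1.11). Of 13 other subunits of the SET1/MLL complexes, 9 were lower and 4 higher, with a median log2 fold of -0.09, inside the range of random lists.

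Genes of the 2-cell-like state, a programme of the early embryo that appears in a small fraction of embryonic stem cells, were the most separated group. Zscan4f was at 2.22 RPKM in the control siRNA library and 41.2 RPKM in the Set1a siRNA library, a ratio of 18.6 (12.6 to 28.5). Zscan4b had a ratio of 23.2 (13.4 to 44.1), Zscan4d of 21.4 (13.2 to 37.3), Zscan4a of 19.1 (12.1 to 32.4) and Zscan4c of 16.3 (11.2 to 24.4). Of the 18 members of the list, 9 were below the floor of 1 RPKM. Of the 9 measured members, 7 were at least 2-fold higher and 0 at least 2-fold lower, and the median log2 fold was 3.47. As 5 of the 9 members are Zscan4 genes, this median is a Zscan4 value: with each near-identical family counted once it was 1.31 over 4 values, and without a floor on expression it was 1.195. The other 2 members past 2-fold were Gm5662, at 4.33 and 25.5 RPKM, and Usp17lc, at 0.531 and 3.40 RPKM. As the floor is set on the mean of both libraries, Usp17lc entered only through its Set1a siRNA value. Sp110 had a ratio of 1.06 (0.690 to 1.63) and Eif1a of 0.926 (0.858 to 0.999). Usp17lc, Sp110 and Eif1a lay outside the naming rule and were chosen after their values were seen. These Zscan4 genes are 96.6% to 99.7% identical in their aligned parts, so reads may be assigned to any copy and the individual values are uncertain. Summed over the 5 genes, 106 control reads stood against 1951 reads, a ratio of 19.1 (15.7 to 23.4). The rule for reads that match several copies is not known. If such a read was counted at each copy, the interval is too narrow, and a rise of 1 copy would appear in several.

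**Figure D1:**
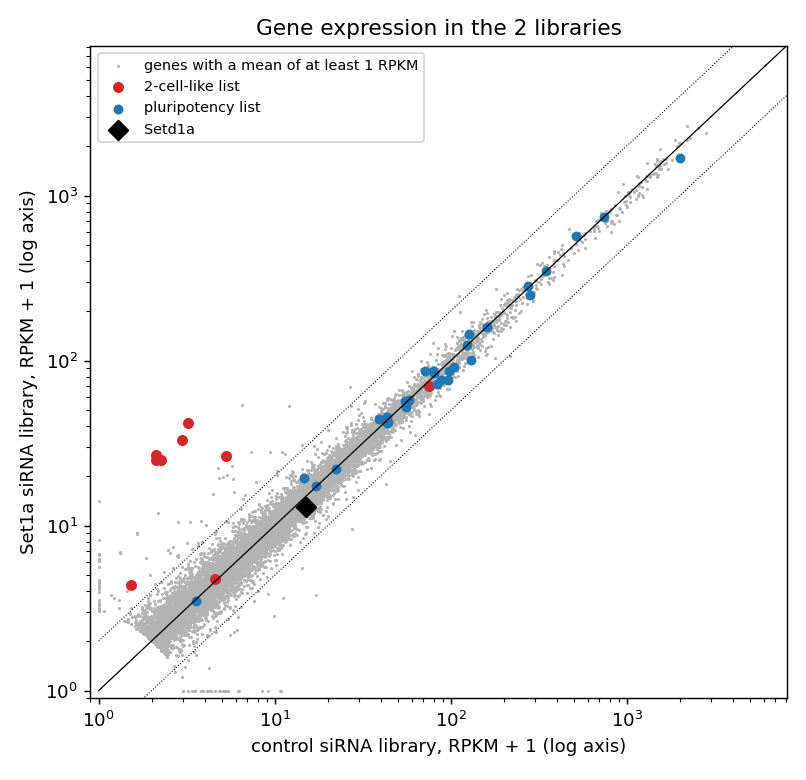
Each point is a gene, with RPKM + 1 in the control siRNA library on the x axis and in the Set1a siRNA library on the y axis, both log axes; the solid line marks equal values and the dotted lines 2-fold. Of the 18 members of the 2-cell-like list, the 9 with a mean of at least 1 RPKM are drawn, and most of these lie far above the line. The 30 pluripotency genes lie close to the line, and Setd1a lies slightly below it at 14.2 and 11.97 RPKM.

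Across the 11786 genes above the floor, the values of both libraries were close. The median log2 fold was 0.0066, with quartiles of -0.14 and 0.15, and 95.6% of genes lay within 1.5-fold. At least 2-fold higher in the Set1a siRNA library were 90 genes, and at least 2-fold lower were 48. Among the higher genes, 29 were under 200 nucleotides long, as were 34 of the lower ones. Simulated counting noise with no change gave on average 25.7 higher and 27.4 lower calls, but 3.3 and 2.75 among transcripts of at least 200 nucleotides, where 56 and 12 genes were observed. The simulation drew each gene independently, without variation between cultures and without reads shared between copies. Of the 90 higher genes, 36 belonged to 13 families of near-identical transcripts, so these numbers do not compare directly. With at least 30 reads over both libraries, 48 higher and 9 lower genes were left.

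Besides the Zscan4 genes, the 12 highest folds at a mean of at least 5 RPKM included Gm4340, with a ratio of 9.60 (7.10 to 13.4), Gm5662, with 5.89 (4.38 to 8.04), Gm8300, with 4.82 (3.51 to 6.72), and 1700030L20Rik, with 4.66 (3.60 to 6.09). Gm4340, Gm5662 and Gm8300 belong to families of near-identical transcripts, so their individual values are uncertain. The 3 others were small RNAs with few reads: Mir293 with 2 control and 11 Set1a siRNA reads, Snora70 with 1 and 10, and Mir1893 with 0 and 7. For Mir1893 the ratio was 2.42 with the limit of 3 reads in place of the 0. That value leaves out the counting error of the 7 reads. Among the 12 lowest folds, Nupr1, a stress-inducible nuclear protein gene, was at 42.0 and 16.9 RPKM, a ratio of 0.403 (0.312 to 0.515). Rpl22l1, a paralog of ribosomal protein gene Rpl22, was at 217 and 106 RPKM, a ratio of 0.490 (0.432 to 0.554). Ubap1l had a ratio of 0.431 (0.264 to 0.684), Cbr4 of 0.484 (0.380 to 0.609), Glipr2 of 0.508 (0.406 to 0.637) and Cox20 of 0.518 (0.349 to 0.759). The remaining 6 were small RNAs. Snord99 had 8 control reads and 1 Set1a siRNA read, and Snord16a had 17 and 5. The counting intervals of Mir25, Snord69, Snord100 and Snord42b included 1.

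Among genes with a mean of at least 50 RPKM, Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, had the largest difference, at 111 and 246 RPKM, a ratio of 2.22 (2.12 to 2.32). Epop, a Polycomb-associated gene, had a ratio of 1.75 (1.65 to 1.86), Upp1 of 1.52 (1.42 to 1.62) and Selenoh of 1.47 (1.27 to 1.70). Lower were Rpl22l1, Ifitm3 with a ratio of 0.578 (0.514 to 0.650), Cth, an enzyme of cysteine synthesis, with 0.631 (0.566 to 0.703), Psat1, an enzyme of serine synthesis, with 0.684 (0.644 to 0.726), and Snhg1, a snoRNA host RNA, with 0.689 (0.586 to 0.808). The intervals of the small RNAs Mir3064 and Mir5114 included 1. Slc2a1 completed these 12 genes.

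The pluripotency genes differed little. Of 30 measured genes of that list, 0 passed 2-fold in either direction, 12 were higher and 18 lower, and the median log2 fold was -0.0095. Pou5f1 was at 745 and 740 RPKM, Nanog at 272 and 281, Zfp42 at 347 and 351, Esrrb at 160 and 158 and Klf4 at 79.5 and 83.7, and the counting interval of each ratio included 1. Sox2 was at 283 and 248 RPKM, a ratio of 0.875 (0.835 to 0.917). Of the lineage markers named in advance, none exceeded 1.25 RPKM in either library. Gata4 was at 0.974 and 0.872 RPKM and Pax6 at 1.11 and 1.25. T had 5 and 7 reads, Fgf5 had 4 and 9, Gata6 had 1 and 7, and Cdx2 was listed at 0 in both. Other lineage genes were well expressed. On the primitive endoderm list, where 5 of 7 measured members were higher, Apoe was at 304 and 274 RPKM, Col4a1 had a ratio of 1.84 (1.57 to 2.16) and Col4a2 of 1.92 (1.49 to 2.53); these 3 were chosen after their values were seen. On the lineage lists, Peg10, of the trophectoderm list, was the gene above the floor that passed 2-fold with 1 RPKM added to each value. It was at 10.4 and 26.1 RPKM, a ratio of 2.51 (2.25 to 2.81).

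Of the 30 lists with at least 5 measured members, 9 stood apart from random lists, 7 above and 2 below. Targets of p53 had a median log2 fold of 0.28, with 17 of 20 members higher. Plk2 had a ratio of 2.16 (1.69 to 2.76), Btg2 of 2.20 (1.63 to 2.99), Ccng1 of 1.58 (1.43 to 1.74) and Phlda3 of 1.56 (1.31 to 1.88). In glycolysis 16 of 19 members were higher, with a median of 0.20. The glucose transporter gene Slc2a1 was at 78.4 and 127 RPKM, a ratio of 1.62 (1.53 to 1.73). The lactate transporter gene Slc16a3 had a ratio of 1.58 (1.44 to 1.72), Ldha, for lactate dehydrogenase, of 1.34 (1.29 to 1.39), and Gpi1 of 1.28 (1.21 to 1.36). Cholesterol synthesis had a median of 0.18, with 16 of 18 members higher, among them Dhcr7 with a ratio of 1.499 (1.21 to 1.86), Mvk with 1.41 (1.09 to 1.82) and Mvd with 1.28 (1.02 to 1.59). Heat shock genes had a median of 0.21, with 11 of 12 higher. Hspa1b and Hspa1a, 99.2% identical, had ratios of 3.88 (2.59 to 5.97) and 3.75 (2.47 to 5.72), while Hmox1 had 1.49 (1.21 to 1.83) and Hspa8 had 1.24 (1.22 to 1.26).

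Immediate early genes had a median log2 fold of 0.24, with 10 of 11 members higher. Spry4 had a ratio of 1.73 (1.55 to 1.94), Egr1 of 1.53 (1.25 to 1.87) and Jun of 2.39 (1.21 to 5.00), while the interval of Fos, 0.910 to 2.88, included 1. Targets of BMP, Nodal and Notch signalling had a median of 0.22, with 9 of 10 higher. Id1 was at 10.1 and 26.8 RPKM, a ratio of 2.67 (1.97 to 3.60), Id3 had a ratio of 1.58 (1.23 to 2.06) and Smad7 of 1.27 (1.13 to 1.42). With the trend in GC content and length removed, this list no longer stood apart, at a median of 0.13. The integrated stress and unfolded protein response list lay below random lists, at -0.19, with 11 members lower and 8 higher, and with its mean in place of its median it no longer did. Chac1 had a ratio of 0.540 (0.421 to 0.685), Atf3 of 0.346 (0.134 to 0.795), Trib3 of 0.674 (0.537 to 0.843) and Psat1 of 0.684. Imprinted genes also lay below, at -0.13, with 9 members lower and 7 higher. Grb10 had a ratio of 0.718 (0.670 to 0.769), the RNA Kcnq1ot1 of 0.735 (0.699 to 0.772) and Rian of 0.763 without an interval, and the interval of Xlr3b, 0.368 to 1.06, included 1. Mest, chosen after its values were seen, went the other way, at 2.84 and 9.68 RPKM, a ratio of 3.41 (2.47 to 4.85). The list median was 0.0066 without a floor and -0.05 with the trend in GC content and length removed, both inside the range of random lists.

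**Figure D2:**
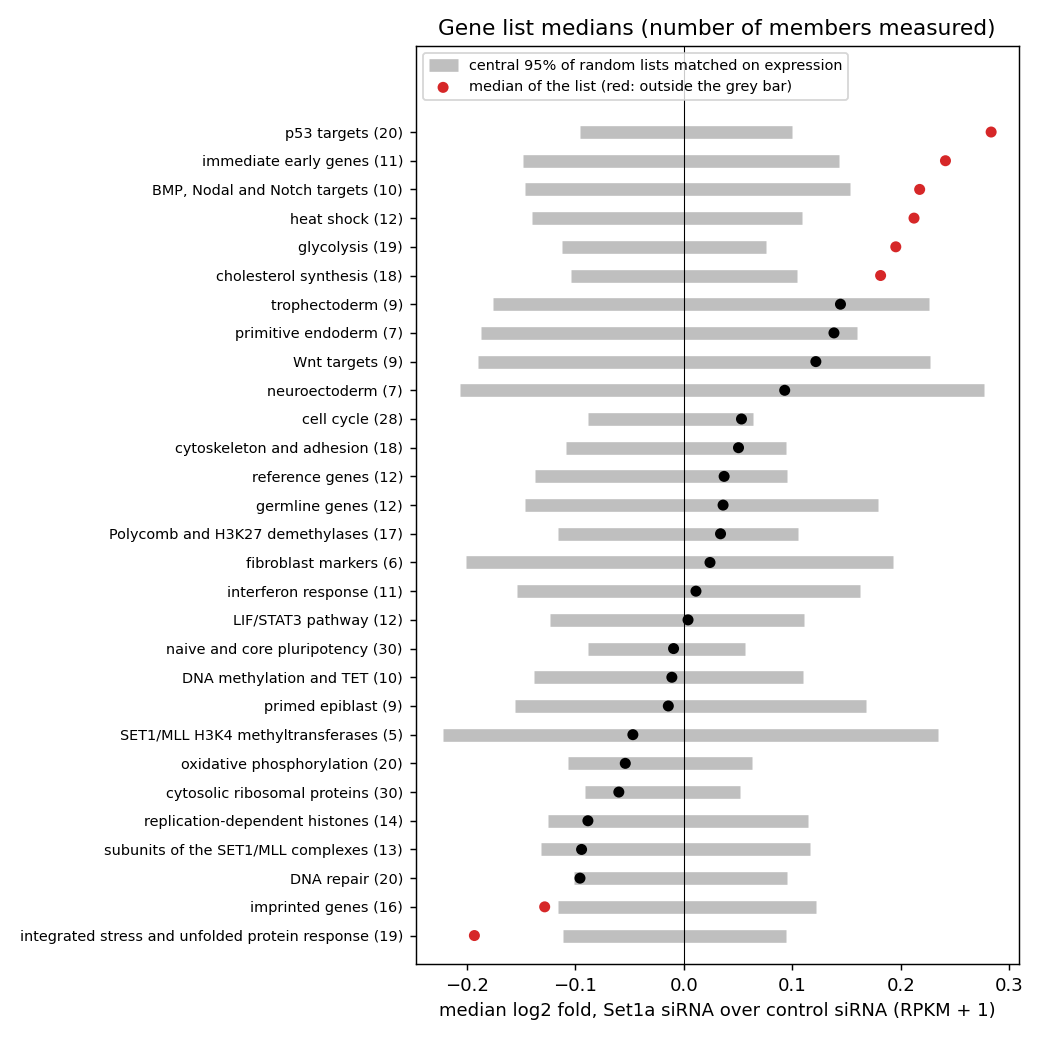
Points are median log2 folds of the Set1a siRNA library over the control siRNA library for gene lists with at least 5 measured members, whose number is in brackets, and grey bars span the central 95% of random lists matched on expression. Red points lie outside their bar; the 2-cell-like list, at 3.47, is off this scale and left out.

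The other 21 lists with a placement lay inside the range of random lists. Medians were -0.10 for DNA repair, -0.09 for replication-dependent histones, -0.06 for cytosolic ribosomal proteins, -0.05 for oxidative phosphorylation, 0.05 for cell cycle genes, 0.03 for Polycomb genes, 0.04 for reference genes and 0.14 for primitive endoderm. With the trend in GC content and length removed, DNA repair, at -0.11, and primed epiblast genes, at -0.16, lay outside it, and as means primitive endoderm, at 0.22, and cell cycle genes, at 0.09, did so. Only 4 mesoderm genes and 1 Hox gene were above the floor, too few for a placement.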

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

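Of 473 transcripts without a gene symbol, which no comparison used, 246 had a mean of at least 1 RPKM. Of these, 5 were at least 2-fold higher in the Set1a siRNA library than in the control siRNA library and 0 were at least 2-fold lower. They drew attention as a signal outside the gene table, above its level in the control. The highest fold belonged to a transcript at 1.29 RPKM in the control siRNA library and 26.5 RPKM in the Set1a siRNA library. By the same rule, 90 of the 11786 genes above the floor were higher and 48 lower, 1.17% in all. At that share, a count of 0 lower among 246 transcripts says little.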

How the results depend on the processing

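Setd1a was lower in all 4 other settings run for it, but these could not have reversed its direction. They changed the pseudocount, or scaled by factors of 1.0019 and 1.0129. Of the 9 lists that stood apart, the 6 above random lists other than BMP, Nodal and Notch targets did so in each of 12 other settings. BMP, Nodal and Notch targets did so in 11, all but the removal of the GC and length trend, and the integrated stress list in 11, all but the mean. Imprinted genes did so in 7, and their median was 0.0066 without a floor and their mean 0.0065, both of opposite sign. Not every setting could change a placement. Scaling moved a list and its random lists nearly alike. The settings on transcript choice, length and read number left the medians of the 6 lists nearly unchanged. The 2-cell-like value ranged from 1.195 without a floor, through 2.22 with a pseudocount of 5 and 2.41 as a mean, to 3.96 with a pseudocount of 0.1. Without a floor, mesoderm genes also stood above random lists, at 0.20. The numbers of genes at least 2-fold higher and lower, 90 and 48, depended on settings. They were 177 and 89 with a pseudocount of 0.1, 37 and 10 with a pseudocount of 5, and 34 and 8 with a floor of 5 RPKM; without a floor they were 131 and 77. A 1.5-fold rule gave 325 and 199, and a 3-fold rule 53 and 29. In alternatives chosen after seeing the data, they were 56 and 12 for transcripts of at least 200 nucleotides, 48 and 9 with at least 30 reads, 58 and 13 with a counting interval that excludes 1, and 67 and 48 with each near-identical family counted once. Of the 90 higher genes, 37 were shared with the call at a pseudocount of 5 and 34 with that at a floor of 5 RPKM. The median of all genes, 0.0066, was near 0 throughout and had no firm sign: 0.014 without a floor, 0.023 with the 50 most abundant genes left out of scaling, -0.0027 with a floor of 5 RPKM and -0.0028 with the GC and length trend removed. The cause of these shifts was not tested. No paired analysis was possible because each group held 1 library. Depth limits short transcripts most, as a small RNA at several RPKM rests on few reads.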

Other observations

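The gene groups in this paragraph and the next were chosen after the data were seen. Their places among random lists therefore describe them and are not separate tests. Also chosen after the data were seen were the tests of shared reads, of library composition and of the integrated stress list. The other tests of GC content and length were set before their results. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 17 were lower in the Set1a siRNA library, with a median log2 fold of -0.20. Sars had a ratio of 0.691 (0.642 to 0.744), Lars of 0.706 (0.660 to 0.755) and Nars of 0.731 (0.690 to 0.774). Of 15 genes of amino acid synthesis and uptake, 14 were lower, with a median of -0.26, including Pck2 with a ratio of 0.654 (0.576 to 0.741). Of 15 chaperone genes of the endoplasmic reticulum, 14 were higher, with a median of 0.26. Hspa5 had a ratio of 1.40 (1.31 to 1.502) and Sdf2l1 of 1.78 (1.34 to 2.39), and both are among 4 chaperone genes that are also members of the integrated stress and unfolded protein response list. Of 17 mitochondrial synthetase genes, 12 were lower and 5 higher, 1 of them by at least 2-fold. Their median was -0.07, inside the range of random lists, but -0.15 and below it with the GC and length trend removed.

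Of the 90 genes at least 2-fold higher, 36 belonged to 13 families of near-identical transcripts, against 1 of the 48 lower ones. Only transcripts of at least 200 nucleotides were searched, a length reached by 56 of the higher and 12 of the lower genes. These counts therefore do not compare directly. As the families were found from genes past 2-fold, their higher sums were in part set by that choice. The 7 near-identical transcripts around Gm4340 had 66 control reads and 685 Set1a siRNA reads in sum, a ratio of 10.8 (8.35 to 14.1). A family of 6 around Pramel16 had 8 and 169 reads, although the 8 measured genes named Pramel had a median of 0.08, with 5 higher and 3 lower, and a family of 6 around Gm428 had 0 and 113 reads. Among gene series taken by symbol, 217 of 326 zinc finger genes of the Zfp series were lower, with a median of -0.09, as were 26 of 38 complex I genes (-0.11), 56 of 78 mitochondrial ribosomal protein genes (-0.07) and 11 of 15 snoRNA host RNAs (-0.33). Each of these 4 medians lay below random lists, and with the GC and length trend removed each still did, at -0.09, -0.12, -0.06 and -0.28. For snoRNA host RNAs the interval of the median over members included 0 both before the trend was removed (-0.51 to 0.032) and after (-0.41 to 0.15). For complex I genes it excluded 0 before (-0.27 to -0.013) and included it after (-0.18 to 0.026). Among small RNAs, C/D-box snoRNAs lay below random lists, at -0.38. H/ACA-box snoRNAs and microRNA precursors lay inside the range, but above it with the trend removed, both at 0.18. Intervals of these small RNA series included 0, and most members held few reads.

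Of the 9 measured members of the 2-cell-like list, 7 were at least 2-fold higher in the Set1a siRNA library, while Sp110 and Eif1a were not. Reads moving between near-identical copies would leave a family's sum about level, but the summed ratio was 19.1 for Zscan4 (15.7 to 23.4) and 4.34 for Usp17l (3.15 to 6.11). The sums do not show how many of the copies rose, as a read may have been counted at more than 1 copy. For the family of Gm5662, which holds the abundant Eif1a, the summed ratio was 1.57 (1.48 to 1.67). It did not clear the bound of 1.5 used for the others. A further measure, taken up after that, put the reads lost by Eif1a at 9.37% of those gained by the other listed copies. Within counting error this share was at most 18.0%, which argues against reads moved out of Eif1a as the main source of that gain. The measure does not address reads shared among the other copies or counted at more than 1 copy. With the trend in GC content and length removed, the list median was 3.50. That trend was small. Among genes of at least 5 RPKM, the median log2 fold was -0.053 for those lowest in GC content and 0.095 for those highest. A trend of that size is too small to make up the list median. For the same reason its removal could not have brought the median under 2-fold, so the removal is no separate test. The Set1a siRNA and the separate culture of each library both stay open, as untested with 1 library per group.

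Medians of the cytosolic synthetases, the amino acid genes and the integrated stress list were lower in the Set1a siRNA library, while the medians of heat shock genes and of endoplasmic reticulum chaperones, which include 4 members of the integrated stress list, were higher. With the GC and length trend removed, the cytosolic synthetase median was -0.24 and remained below random lists, as did that of the amino acid genes, at -0.30. The integrated stress list had a median of -0.19 before this correction, with an interval of -0.42 to 0.25 over its members. After it the median was -0.25 (-0.44 to 0.23), still below random lists. Both intervals included 0, so the spread of the members left the sign open with or without the trend. In a further measure, taken up after that, the trend itself had a median of 0.023 over the members (-0.0076 to 0.060). This is far from -0.19 and argues against the trend as the source of the low median, although the members themselves went both ways. Composition of the libraries would move reference genes alike, yet their median lay 0.24 above that of the synthetases. This comparison was chosen after the data were seen, so it describes the gap and is not a separate test. Gapdh and Pgk1, of the reference genes, are also on the glycolysis list, whose median was higher. Amino acid supply in the medium at harvest may differ between cultures and was not tested, and the siRNA itself stays open as well.

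The list medians of glycolysis, p53 targets and heat shock were higher in the Set1a siRNA library. With 1 RPKM added to each value, Hspa1a and Hspa1b were the members past 2-fold. Plk2 and Btg2, p53 targets with ratios of deposited RPKM above 2, fell short by that rule. Folds increased with GC content across genes (Spearman rho 0.21 over 11661 genes, which are not independent replicates). With the GC and length trend removed, the medians were 0.16 for glycolysis, 0.27 for p53 targets and 0.20 for heat shock, and each stayed above its random lists, which argues against that trend as the whole cause. Culture density, transfection stress and the Set1a siRNA could each contribute and cannot be separated with 1 library per group.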
